A study of Galleria mellonella with 3 samples.

How the data were processed

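Small RNA was sequenced from whole larvae of the greater wax moth, Galleria mellonella, after injection with the uropathogenic Escherichia coli strain CFT073, with the strain ABU83972, or after mock injection. Total RNA was extracted with a Qiagen miRNeasy Mini kit, per the labels' protocols. Each of the 3 groups had 1 library. Groups were taken from the infection label of each sample.

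The authors deposited a table of miRNA hairpins predicted by miRDeep2, per the file headers, in which whole-number read counts are listed for the mature arm, the loop, the star arm and their total. The deposited counts are raw, and no column names a library. Which of the 3 libraries entered them is not given in the sources used here. Per the file headers, each hairpin also has a miRDeep2 score, on which a higher value ranks a hairpin as a more probable precursor. The same table opens with an estimated signal-to-noise ratio at each score threshold and an excision gearing of 4, per the file headers. The deposited hairpin positions lie on contigs of the draft genome whose names begin with NTHM01. The deposited start positions count from 0, since end minus start equals the hairpin length for every hairpin, and starts are printed here counted from 1. The trimming, mapping settings and program versions are not given in the sources used here.

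The authors deposited a second table of predicted miRNA target sites, made with microPIECE, which transfers regions bound by Argonaute in another species to the transcripts of the species of interest. Per the file headers, each site has an alignment score, a free energy in kcal/mol and an alignment identity in percent. Identity was not used here. Transcripts have assembler names that the deposited table does not pair with genes. Of these names, 0 matched the gene table of assembly CSIRO_AGI_GalMel_v1, and 0 of the contigs matched it by name, so the planned test of immune transcript lists was not run.

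The 2 tables carry different names for the miRNAs. In the target table a miRNA is named gme-new followed by a number and its arm, and identical sequences share a joined name. These numbers were taken as the order of the hairpin table, which the sources used here do not state. All 257 sets of identical sequences in the target table were the sets that this order predicts, against at most 141 over 1000 shuffles of the numbers. The furthest aligned base fell 1 base short of the sequence length for 255 of the 257 names, against at most 102 over the shuffles, and for 0 names did it reach or pass that length.

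Because counts were not split by library, no value per group, no depth per library and no difference between infected and mock-injected larvae could be computed. The planned comparisons of CFT073 with mock, ABU83972 with mock, and CFT073 with ABU83972 were therefore not made, and the planned description of the pooled tables was used. Before the data were examined, the lists of miRNA families, the rule for the miRNAs to be named, the tests and most alternatives were fixed. The named miRNAs are the 15 with most reads, the 5 with the highest and the 5 with the lowest miRDeep2 score, every member of 10 family lists, the 5 miRNA sequences with most and the 5 with fewest target transcripts, and the 10 transcripts with most miRNAs. Ties went by name, and the 10 transcripts are summarised because their names identify no gene. List members were matched on bases 2 to 8 of the mature sequence (the seed) or on the family name of the miRBase miRNA that the deposited table gives as sharing the seed. The seed of each family was written down after the tables had been seen. Other miRNAs named in the text were chosen after their values were seen. The limits of 1000 reads and of a score of 6, used to describe scores, were also set after the values were seen.

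A mature sequence listed at several hairpins was counted once, at the hairpin with most reads, for shares of reads. Shares have Wilson 95% intervals. Intervals cover counting error only, since reads carried no molecular identifiers that are described in the sources used here. The arm with more reads was compared between the 5' and 3' sides over hairpins with at least 50 reads by a two-sided exact binomial test. The mature arm is by definition the one with at least as many reads, and 0 hairpins had more star than mature reads. Hairpins on 1 contig and strand whose starts lay within 10 kb of the next formed a cluster. Pearson's r and Spearman's rho of the number of predicted sites with log2(reads + 1), GC content and length were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over the 3 relations. On simulated data of the same size, the test of rho, with 1000 permutations each, called 3.5% of 200 data sets without a relation, 87.5% at a correlation of 0.2 and 100% at 0.5. The binomial test called 4.1% of 1000 simulated sets of 100 hairpins without a preference and 82.7% with a share of 0.65.

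The alternatives were score minimums of 5 and 10, hairpins with a significant randfold p only, distinct sequences counted once, cluster distances of 2 and 50 kb, read minimums of 10 and 200, only sites at least as good as the median free energy or the median alignment score, and transcripts in place of sites. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.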

Results

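Small RNA libraries were made from Galleria mellonella larvae infected with the uropathogenic strain CFT073, larvae infected with the strain ABU83972, and mock-injected larvae, with 1 library in each of the 3 groups. The series asks how miRNAs take part in the innate immune response of this surrogate insect host to uropathogenic and commensal-like E. coli. The deposited counts were not split by library, so the values that follow describe the miRNAs of these larvae as 1 pool of unstated libraries, without replicates, and no miRNA was compared between the infections and the mock injection. The table listed 161 candidate hairpins on 102 contigs, with 125 distinct mature sequences. Reads summed to 1906520 with each mature sequence counted once, and a hairpin had a median of 386 reads, from 3 to 491420.

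The most abundant miRNA was gme-new-1, which carries the seed of miR-8, a regulator of growth and insulin signalling in the insect fat body. Its 491420 reads were 25.8% of all reads (95% interval 25.7 to 25.8). It was followed by gme-new-3 with the seed of miR-276a, at 261667 reads, and by gme-new-4, at 140132 reads, which carries the seed of the growth-promoting bantam and of cel-miR-80. The miR-276a seed sequence made up 13.7% of reads (13.7 to 13.8) and the bantam seed sequence 7.35% (7.31 to 7.39). With gme-new-5 (seed of cel-miR-57, 113810 reads) and gme-new-6 (seed of the muscle miRNA miR-1, 101759 reads), the leading 5 sequences held 58.2% of all reads.

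The next sequences each had between 34414 and 71106 reads. They were gme-new-7 with the miR-2 seed at 71106 reads, gme-new-91 with the cel-miR-72 seed at 68903, gme-new-8 with the miR-750 seed at 56721 and gme-new-106 with the miR-184 seed at 55254. The seed that miR-263a shares with miR-183 was on gme-new-9 at 49600 reads. The miR-14 seed, of a miRNA that limits cell death in flies, was carried by both gme-new-11 at 43408 reads and gme-new-101 at 34414. The seed of cel-miR-46 and miR-281 was on gme-new-12 at 37901 reads, that of miR-314 on gme-new-14 at 35540, and that of cel-miR-44, miR-279 and miR-286 on gme-new-15 at 34583. Together the leading 15 sequences held 83.7% of reads, whereas 53 of the 125 sequences had under 100 reads. Mature sequences had a median length of 22 bases, from 19 to 25, and 103 of the 125 were 21 to 23 bases long. A uridine was the first base in 76 of 125, or 60.8% (52.0 to 68.9).

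**Figure D1:**
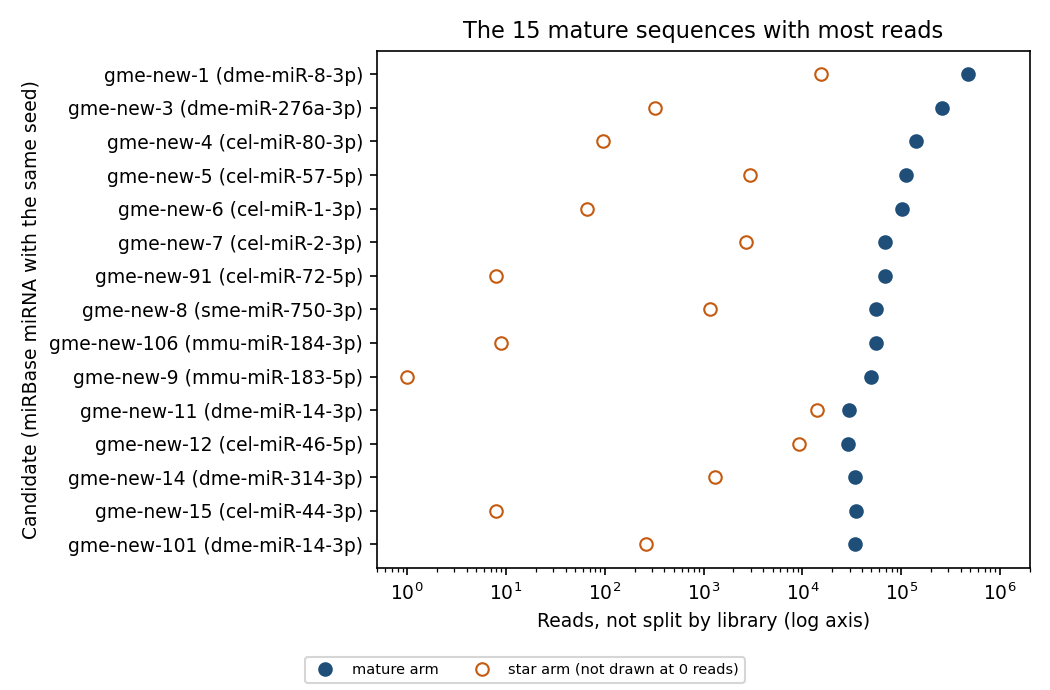
Reads of the mature arm (filled) and the star arm (open) on a log axis for the 15 mature sequences with most reads, each with the miRBase miRNA that shares its seed. The mature arm of gme-new-1 stood at 476106 reads and its star arm at 15299, and the arms lay closest for gme-new-11, at 29448 and 13960.

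All 10 families of the list reported to act on insect immune genes had a member by seed, 14 sequences in all with the 2 matched by name only. They held 38.6% of reads (38.5 to 38.6), of which the miR-8 and bantam seed sequences made up 85.9%, and the others held 5.44% of all reads (5.41 to 5.48). Beyond the miR-8 and bantam seeds, gme-new-130 with the miR-958 seed had 27676 reads. The miR-9 seed was on gme-new-17 with 25195 reads and gme-new-22 with 16807. The seed of let-7, which times the larval to adult transition, was on gme-new-95 with 12906 reads, and that of miR-317 on gme-new-27 with 11406. Lower counts were found for the seeds of miR-277 on gme-new-34 (5011 reads) and miR-34 on gme-new-38 (3640 reads). The miR-92 seed was carried by gme-new-60 (600 reads) and gme-new-64 (411 reads), and the miR-981 seed by gme-new-109 (72 reads). Matched by name only were gme-new-98, with 55 reads and the seed partner sme-miR-277d-5p, and gme-new-147, with 8 reads and the seed partner bma-miR-9-5p, although both mature sequences lay on the 3' arm.

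Growth and moulting families held 40.0% of reads (40.0 to 40.1), with 6 of 8 seeds found, and the same miR-8 and bantam seed sequences made up 82.7% of these reads. Besides miR-8, bantam, let-7 and the pair of miR-14 sequences, they included gme-new-12, which has the 5' seed of miR-281, a regulator of an ecdysone receptor isoform in silkworm, and gme-new-40 with the miR-252 seed at 3218 reads. The 3' seed of miR-281 was not found at bases 2 to 8 of a mature sequence, but stood 1 base later, from base 3, on the star arm of gme-new-12, with 9209 reads. The seeds of miR-100 and miR-125, the usual companions of let-7, were found on 0 mature or star sequences, so 1 of the 3 families of the let-7 list was matched.

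The lists of tissue families differ in size and each was led by few sequences, and they were not tested against each other. The muscle list held 5.44% of reads (5.41 to 5.48), nearly all from the miR-1 seed sequence, with 2013 reads for gme-new-46, which has the seed of miR-133. The neuronal list held 0.166% (0.160 to 0.172), from 3070 reads of gme-new-129 with the miR-7 seed and 91 reads of gme-new-111 with the miR-124 seed. The miR-315 seed was on 0 mature sequences and stood 1 base late on a star arm with 11 reads. The gut, fat body or epithelium list held 33.0% (33.0 to 33.1), and 7.26% (7.23 to 7.30) without the miR-8 seed sequence, which the immune and growth lists also hold. Beyond miR-8, miR-263a and miR-281, it included the miR-275 seed on gme-new-19 (22387 reads), the miR-278 seed on gme-new-21 (21394 reads) and the miR-263b seed on gme-new-62 (562 reads). The miR-275 seed was also on gme-new-30 (6618 reads), but there the mature sequence is the 5' arm, not the 3' arm as in miR-275, and the hairpin lies 2629 bases from the miR-9 seed hairpin gme-new-17, on another contig than gme-new-19. The miR-305 seed, the second family of the miR-275 list, was on 0 sequences. That list held 29005 reads by seed, 1.52% of all, with gme-new-30 included.

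By seed, the germ line and embryo list held 3.22% of reads (3.19 to 3.24), but 0.0606% (0.0572 to 0.0642) without the miR-286 seed. That seed is also the seed of miR-279 and cel-miR-44, and a seed match does not tell these families apart. It was on 4 sequences: gme-new-15 with 34583 reads, gme-new-25 with 14855, gme-new-28 with 8295 and gme-new-43 with 2434. The Hox-cluster miRNA miR-iab-4 was represented by gme-new-105 with 145 reads, and the seeds of miR-309 and miR-iab-8 were on 0 sequences.

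Several families known to be clustered in insects lay together on 1 contig. On the minus strand of contig NTHM01000459.1, 5 hairpins of the miR-2 family stood between positions 50187 and 50780. They were gme-new-29 with 7767 reads, gme-new-36 with 4926, gme-new-49 with 1382, gme-new-53 with 1198 and gme-new-32 with 6448. The mature sequence that gme-new-32 and gme-new-36 share was matched by name only, through sme-miR-2b-3p, and has another seed. On the same strand, gme-new-48, whose star arm carries the miR-71 seed, lay from 64914 to 64974. Its 3' arm, in the seed of tca-miR-71-3p, had 1348 reads against 231 on the 5' arm. The miR-2/13/71 list as a whole held 4.74% of reads (4.71 to 4.77), and 4.31% by seed alone. Most came from gme-new-7, which lay elsewhere, on NTHM01000012.1 from 3114818 to 3114872. Its match rests on the seed, which does not show that gme-new-7 belongs to the miR-2 family. A further miR-2 seed sequence, gme-new-55, had 801 reads.

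**Figure D2:**
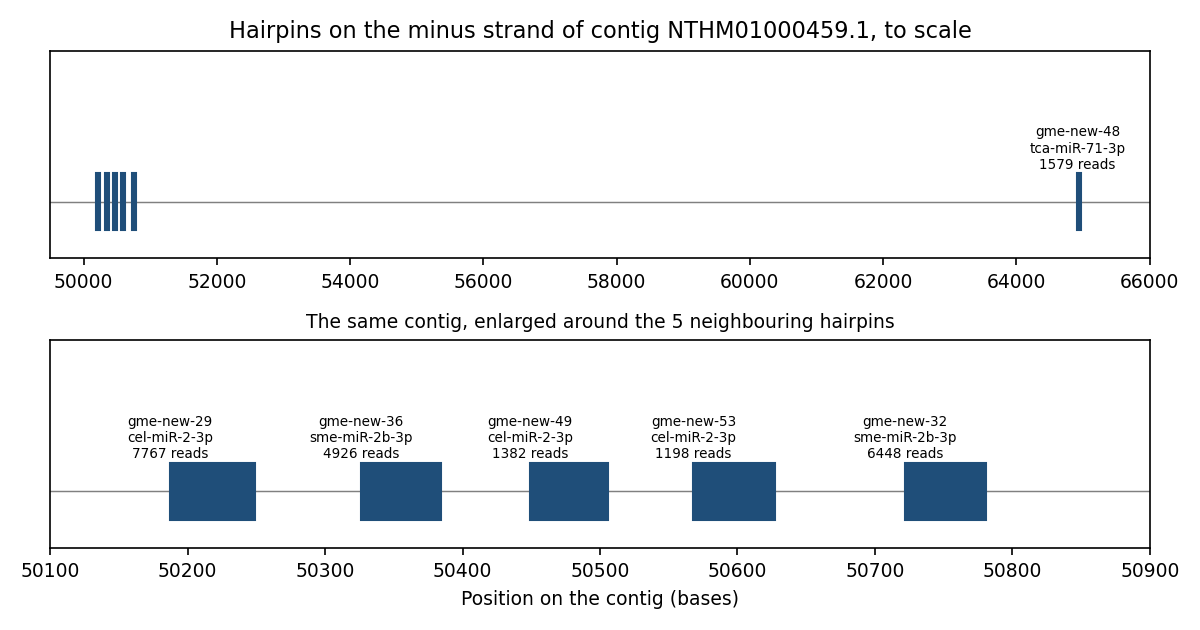
Hairpins on the minus strand of contig NTHM01000459.1, drawn to scale by position in bases, with the reads of each. The 5 miR-2 family hairpins lie between 50187 and 50780, and the miR-71 hairpin gme-new-48 starts at 64914.

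The hairpins with the miR-317, miR-277 and miR-34 seeds lay in this order on the plus strand of NTHM01000144.1, at 716894 to 716956, 740058 to 740141 and 758879 to 758937. Their list held 1.05% of reads (1.04 to 1.07). The miR-1 and miR-133 seed hairpins were 19976 bases apart on the minus strand of NTHM01000055.1, and those with the miR-750 and miR-958 seeds were 147 bases apart on NTHM01000077.1. These miR-317/277/34 and miR-1/133 groups and the miR-71 hairpin lie further apart than 10 kb and belong to the 20 clusters, with 55 hairpins, that form within 50 kb. With starts within 10 kb of the next, 18 clusters held 44 of the 161 hairpins. Of these clusters, 4 held a single mature sequence at several hairpins, and with repeated sets on other contigs counted once, 12 sets of at least 2 mature sequences were left. No annotation of these contigs was used here, so the genes around the hairpins are not given.

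In most hairpins 1 arm accounted for nearly all reads. Over the 101 hairpins with at least 50 reads, the mature arm had a median of 99.2% of mature and star reads, and 53 hairpins reached at least 99%. The mature arm stayed under 75% in 8 of the 81 distinct sequences, whose mature arms had from 44 to 29448 reads. Among the abundant ones were gme-new-25 with the miR-279 and miR-286 seed at 59.9% (59.1 to 60.7), gme-new-11 with the miR-14 seed at 67.8% (67.4 to 68.3) and gme-new-17 with the miR-9 seed at 72.5% (71.9 to 73.0). The other miR-14 seed sequence, gme-new-101, had 99.2% on its mature arm (99.1 to 99.3), and the other miR-9 seed sequence, gme-new-22, 94.3% (94.0 to 94.7). The mature arm was the 3' arm in 64 hairpins and the 5' arm in 37, or 63.4% (53.6 to 72.1), which differed from equal use (two-sided exact binomial p = 0.00934 across hairpins, which are not independent replicates). Some of these hairpins share a mature sequence. With each distinct sequence counted once, the 3' arm led in 52 of 81, or 64.2% (53.3 to 73.8; two-sided exact binomial p = 0.0140).

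The miRDeep2 score followed the read count for most abundant miRNAs and stayed low for some. The 5 highest scores belonged to gme-new-1 (250543), gme-new-3 (133408), gme-new-4 (71446), gme-new-5 (58027) and gme-new-6 (51884). Among 67 hairpins with at least 1000 reads, 54 scored at least 565.9, and 13 scored 5.6 or less. The low-scoring ones included the hairpins with the cel-miR-72 seed (gme-new-91, 5.6), the miR-184 seed (gme-new-106, 5.0), the let-7 seed (gme-new-95, 5.5), the miR-958 seed (gme-new-130, 3.8) and the miR-7 seed (gme-new-129, 3.8). The lowest scores of the table were 0 for gme-new-161 (69 reads), 0.5 for gme-new-160 (23 reads), 0.6 for gme-new-159 (68895 reads), and 0.9 for both gme-new-157 (4 reads) and gme-new-158 (449 reads). The deposited signal-to-noise ratio was 34.6 at a score of 10, 27.5 at 5 and 3.2 at 0. A minimum score of 5 kept 106 hairpins and a minimum of 10 kept 84, and the latter leaves out the let-7, miR-184, miR-958 and miR-7 seed hairpins.

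**Figure D3:**
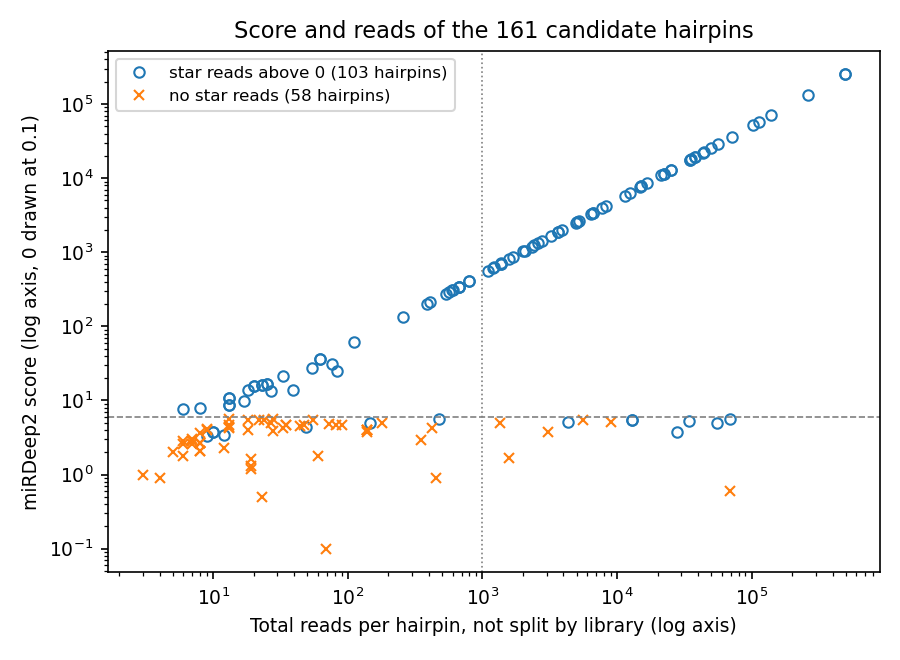
miRDeep2 score against total reads, both on log axes, for the 161 hairpins. Circles mark hairpins that have star reads and crosses the 58 that have none, and a score of 0 is drawn at a small positive value. The dashed line is a score of 6 and the dotted line 1000 reads, and 13 hairpins lie to the right of the dotted and under the dashed line.

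Predicted targets were spread over abundant and scarce sequences, mature and star arms alike. The table listed 6979 sites for 257 mature and star sequences in 1898 transcripts, with a median of 25 sites per sequence, from 2 to 81. The miR-8 seed sequence gme-new-1-3p had 46 target transcripts, the bantam seed sequence gme-new-4-3p 26, the miR-276a seed sequence gme-new-3-3p 18 and the let-7 seed sequence gme-new-95-5p 19. Fewest transcripts were predicted for the star arm gme-new-45-3p (2), gme-new-96-3p (4) and the miR-184 seed sequence gme-new-106-3p (6). The star arms gme-new-11-5p of a miR-14 hairpin and gme-new-19-5p of a miR-275 hairpin had 6 each. Most were predicted for the star arm gme-new-135-3p (79, with 5 reads) and the mature arm gme-new-70-3p (77, with 68 reads). The former is 30 bases long, and its hairpin had equal reads on both arms. The star arms gme-new-139-5p (72), gme-new-110-5p (68) and gme-new-108-3p (66) came next, each with 0 reads.

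Across the 257 sequences, which are not independent replicates, the number of sites was not related to reads past the threshold (rho = -0.0965, permutation p = 0.124, adjusted p = 0.124; r = -0.115, p = 0.0673). It fell with GC content (rho = -0.522, r = -0.481, both with permutation p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 3e-05). The 86 sequences lowest in GC content had a median of 35 sites, and the 86 highest 18. The number of sites rose with length (rho = 0.217, p = 0.00047, adjusted p = 0.000705; r = 0.222, p = 0.00038). Without the 2 sequences farthest from the median, r was -0.127 for reads, -0.506 for GC content and 0.203 for length. Among the 3493 sites with a free energy at or under the median of -13.72 kcal/mol, the relation with GC content turned to positive (rho = 0.254, adjusted p = 0.000105).

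**Figure D4:**
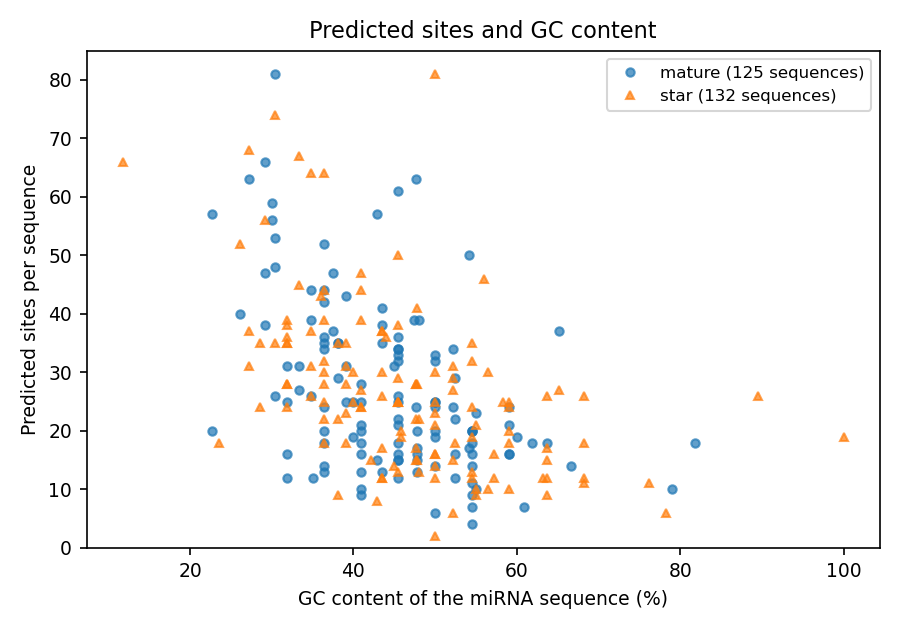
Predicted sites per sequence against GC content in percent, for 125 mature (circles) and 132 star (triangles) sequences. Sites fell with GC content, with rho = -0.522 over the 257 sequences.

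Target transcripts differed widely in how many mature and star sequences were predicted to bind them, and in how many target regions they held. A transcript had a median of 2 miRNA sequences, 594 of the 1898 had 1, and 132 had at least 10. Transcripts had a median of 2 target regions, and the 917 with 1 region had a median of 1 miRNA sequence. The highest number was 31, for CUFF.16465.1.p1 with 34 sites in 15 regions and CUFF.44242.1.p1 with 33 sites in 18 regions. The leading 10 transcripts had between 26 and 31 miRNA sequences, in 12 to 18 regions. The table does not pair these names with genes, so none was assigned to an immune pathway.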

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

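Reads of the hairpin loop lie outside the arm shares and the target table, and no test was run on them. In 8 hairpins their number exceeded 3, a fixed floor. No background of loop reads was estimated, so passing the floor does not separate signal from noise. The most were 74 loop reads for gme-new-103 with the cel-miR-67 seed, beside 4245 mature and 6 star reads. Loop reads exceeded mature reads in gme-new-114, with 55 against 26, and in gme-new-161, with 43 against the same 26, and both hairpins had 0 star reads and share their mature sequence. Both copies of the miR-8 seed hairpin, gme-new-1 and gme-new-2, had 15 loop reads. The remaining values were 10 for gme-new-14 with the miR-314 seed, 6 for gme-new-95 with the let-7 seed and 4 for gme-new-29 with the miR-2 seed. Loop reads of all hairpins summed to 240.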

How the results depend on the processing

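The test of the dominant arm at a score of at least 5 was chosen after the data were seen. Of 22 alternatives, 19 kept the side of the threshold, or a count within 1.5 times, and none of these called a changed direction. The catalogue of 161 hairpins moved to 106 at a miRDeep2 score of at least 5 and to 84 at a score of at least 10, because fewer hairpins were counted. The fall of predicted sites with GC content reversed to a rho of 0.254 among sites with a free energy at or under the median. That setting selects on energy, and the median energy of a sequence itself fell with GC content (rho = -0.739, permutation p = 1e-05, the smallest that 100000 permutations can give). Under the other alternatives, the share of 3' mature arms ranged from 61.9% to 65.1%, with binomial p from 0.00403 to 0.0375, and rho ranged from -0.523 to -0.479 for GC content. For length, rho ranged from 0.198 to 0.266, and the relation with reads was not past the threshold under any alternative run, although its rho changed sign to 0.0616 among the sites of low free energy. No paired analysis was possible because the counts were not split by library. For the same reason the scaling alternatives for comparisons between groups and for the family lists were not run, nor were those for immune transcripts, whose names identify no gene. Counts under 50 reads limit the arm shares, and 53 of the 125 mature sequences had under 100 reads.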

Other observations

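The tests of low scores, of hairpins on several contigs and of mature against star arms were chosen after the results were seen, as was the use of the planned relation with GC content to weigh base composition. A few hairpins lay on both strands of 1 locus or overlapped. The miR-8 seed hairpin gme-new-1 on NTHM01001021.1 faced gme-new-131 on the opposite strand, with 10 reads against 491420. On NTHM01000053.1, the hairpins gme-new-159 (1250219 to 1250281) and gme-new-91 (1250261 to 1250319) overlapped and were assigned the same mature sequence with the cel-miR-72 seed, as the 3' arm of the former and the 5' arm of the latter. Only the latter had star reads, 8 in number. On NTHM01000518.1, 7 hairpins spread over 53350 bases of the minus strand had between 8 and 33 reads each.

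Low miRDeep2 scores fell on 13 hairpins with at least 1000 reads, among them those with the let-7, miR-184, miR-958 and miR-7 seeds. Missing star reads cannot account for all of them, since 7 of the 13 had star reads. For the other 6 that explanation stays open. Of the 58 hairpins without star reads, 0 scored 6 or more, and the highest score was 5.7. The limit of 6 was set after the scores were seen, so this count lends no support. A second candidate explanation is a shorter mature sequence, as the low-scoring ones averaged 20.8 ± 1.08 bases (SD, n = 11 distinct sequences) against 22.4 ± 0.900 (SD, n = 43), a difference of -1.55 bases (95% bootstrap interval -2.22 to -0.890; two-sided permutation p = 4e-05). Of these 11 sequences, 5 were 20 bases or shorter, against 0 of the 43. Whether any was truncated from a longer form was not measured. The miR-958 seed hairpin, with a mature length of 22 bases and 1883 star reads, had neither feature, and no biological explanation was tested.

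Of the 125 mature sequences, 26 had hairpins on more than 1 contig, including those with the miR-8, let-7, miR-9 and miR-34 seeds, and the miR-8 locus counts for both of its strands (gme-new-1 and gme-new-131). Chance matches to unrelated sites are argued against by the loops, which neither the shared mature sequence nor its pairing fixes, since 0 of the 26 had loops no more alike than the 95th percentile of unrelated loops, 56.2% identity over 7727 pairs. The median identity of their loops was 100%, and the lowest was 63.6%, for gme-new-137 with a loop of 11 bases. A median this high would arise from 1 locus assembled on separate contigs. A recent duplication stays open, as the 3 contig pairs that shared at least 2 of these sequences at separate loci would arise either way. Spacing in these pairs was 2166 against 2629 bases (gme-new-18 to gme-new-31) and 18821 against 14013 (gme-new-34 to gme-new-39). It was equal at 124 (gme-new-31 to gme-new-51) and 140 (gme-new-87 to gme-new-113). A single locus per contig does not account for gme-new-123, with 4 hairpins on 2 contigs. Counting every hairpin would add 754435 reads, 28.4% of the summed total. That value covers all 32 sequences at more than 1 hairpin, including 6 on 1 contig only. No biological explanation was tested.

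Base composition of the miRNA is a candidate explanation for the number of predicted sites per sequence, with a rho of -0.522 against GC content (95% bootstrap interval -0.611 to -0.424). The relation turned to 0.254 among sites with a free energy at or under the median, so it holds only for the full set of sites. That subset selects on energy, which itself fell with GC content (rho = -0.739), so the turn cannot weigh for or against base composition. Whether the arm that was sequenced more has more sites stays open. Over 125 hairpins the mature arm had 27.2 ± 14.8 sites and the star arm 26.4 ± 14.1 (SD), a mean difference of 0.832 (95% bootstrap interval -2.31 to 3.99; two-sided permutation p = 0.611), an interval that allows a difference either way. The mature arm had more sites in 66 hairpins and the star arm in 57, while the medians were 24 and 25. No biological explanation was tested, and the base composition of the transcripts was not analysed here.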
